A study of Mus musculus with 5 samples.

How the data were processed

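The series holds 5 ChIP-seq samples of mouse embryonic fibroblasts. Peak lists of 3 of them were used, from cells overexpressing E2F1, E2F3A or E2F3B. The other 2, titled 1KO_MEF and 3KO_MEF in the labels, were not analysed here. Per the labels' protocols, sonicated chromatin was precipitated with antibody, libraries were made from the precipitated DNA with Illumina's TruSeq ChIP kit with PCR amplification, and a narrow size range was cut from a gel. Samples were grouped by the overexpressed protein in the labels, which gave 1 library per group.

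The submitters' processing notes name Bowtie2, SAMtools and the genome build mm9, with no versions. The peak names in the deposited files carry the name of the peak caller MACS. Its version, its threshold, the control it was given, and whether the knockout samples served as that control are not given in the sources used here, nor is the handling of PCR duplicates. A different control or threshold would change how many peaks a list holds and therefore every share. Each deposited list gives the chromosome, start, end and name of a peak, called per sample, and the files used hold no score, fold enrichment, p-value, summit or read count. Peak width therefore took the place of a score, as fixed before the data were examined. The depth per sample was unknown, and no interval that needs it was made.

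Chromosome 7 had peaks up to position 152452391, and 36 peaks lay past the last chromosome 7 gene of GRCm38, the build of the gene table at hand, so positions of that table were not used. No genome or annotation of mm9 was used. The planned shares of promoter peaks, E2F motif shares, gene list enrichments and overlaps of bound genes were therefore not computed, nor were the alternatives that rest on start sites. Starts were taken to count from 0, as in the BED format, and 1 was added for printing. A start may be off by 1 bp if the files count from 1.

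Peaks of 2 lists were called shared when they overlapped by at least 1 bp. The share was set against 1000 placements of the counted list, shuffled without overlap within each chromosome with bedtools 2.31.1, with a one-sided permutation p. Placements were limited to the span from the lowest start to the highest end of any peak on that chromosome, and the same spans gave the densities per Mb. These spans include assembly gaps and sequence to which reads cannot be aligned. Shares of peaks have 95% Wilson intervals. The difference between the shares of E2F3A peaks in the E2F3B and E2F1 lists has a percentile interval from 10000 bootstrap draws of 5 Mb blocks. This comparison was added after the data were seen. Median widths of shared and unshared peaks were compared with a two-sided permutation test of 100000 resamples, adjusted by Benjamini-Hochberg over 6 tests. Merged regions join peaks of any list that overlap. Correlations across chromosomes used 100000 permutations, two-sided, with adjustment over 10 relations. Scripts ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

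Named regions followed a rule fixed before the data were examined, for the case without an annotation: the 5 widest peaks of each list and the 5 widest regions common to all lists. Alternatives fixed at the same time were peak centres within 100 bp, a reciprocal overlap of at least 50%, peaks within 500 bp, the 50% widest peaks of each list, the 1998 widest peaks of each list, and autosomes and X only. Chance from shifts of 20 to 500 kb was added later. The overlap count was tested on simulated data for each pair of lists: in 9 simulated sets the planted overlap was recovered to within 0.209 percentage points, and 0 of the 3 sets without planted overlap had a p under 0.05. Planted peaks were centred close to their targets, and all other peaks were placed by the same shuffling as in the test. These sets therefore check the counting and not the p-value for clustered peaks. The width test called 3 of 60 simulated sets without a difference and returned 31 bp for a planted shift of 30 bp.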

Results

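Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate E2F proteins on the genome of mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos. The cells were proliferating without synchronization and stably overexpressed E2F1, E2F3A or E2F3B. E2F1 and E2F3 are transcription factors that bind the promoters of genes for DNA synthesis and cell cycle entry, and E2F3A and E2F3B are products of the same gene that differ at their N-terminus. E2F1 was precipitated with an antibody against E2F1, and both E2F3 isoforms with 1 antibody against E2F3. Each list is named by the overexpressed protein. E2F1 or E2F3 that the cells may have made from their own genes, and antibody background, could not be told apart from it. Each of the 3 proteins was represented by 1 library with 1 peak list. The other 2 samples of the series, titled 1KO_MEF and 3KO_MEF and precipitated with the E2F1 and the E2F3 antibody, had no peak list among the files used and were not analysed here. With 1 library per protein there was no replicate spread, so each comparison describes these libraries. Intervals of shares and of peak ratios cover counting error of peaks only, and no interval covers the spread between libraries. The lists carried no read counts, so the depth behind a peak was unknown, and a region missing from a list was not called there, which does not show that it was unbound.

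The lists differed in length and in peak width. The E2F3B list held 4704 peaks, the E2F1 list 3787 and the E2F3A list 1998. E2F1 peaks were the widest, with a median of 605 bp (quartiles 516 and 749 bp). E2F3B peaks had a median of 356 bp (298 and 447 bp) and E2F3A peaks a median of 341 bp (289 and 378 bp). Together the E2F1 peaks covered 2.47 Mb, the E2F3B peaks 1.82 Mb and the E2F3A peaks 0.697 Mb. Each list reached 20 chromosomes, the autosomes and X. The peak width depends on the fragment length and the caller as well as on the bound site, and the lists were not normalized to each other. A difference in width between lists therefore does not by itself show a difference in binding.

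The first question was whether the 3 lists covered the same regions. Merging overlapping peaks of the 3 lists gave 7852 regions, of which 642 (8.18%) held a peak of all 3 lists. A further 1002 regions (12.8%) were called for E2F1 and E2F3B, 185 (2.36%) for E2F3A and E2F3B, and 57 (0.726%) for E2F1 and E2F3A. The remaining regions were called for 1 protein, namely 2784 for E2F3B, 2082 for E2F1 and 1100 for E2F3A. In each list the peaks found in no other list formed the majority, at 59.2% of E2F3B peaks (95% Wilson interval 57.8 to 60.6), 55.1% of E2F3A peaks (52.9 to 57.2) and 55.0% of E2F1 peaks (53.4 to 56.6).

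**Figure D1:**
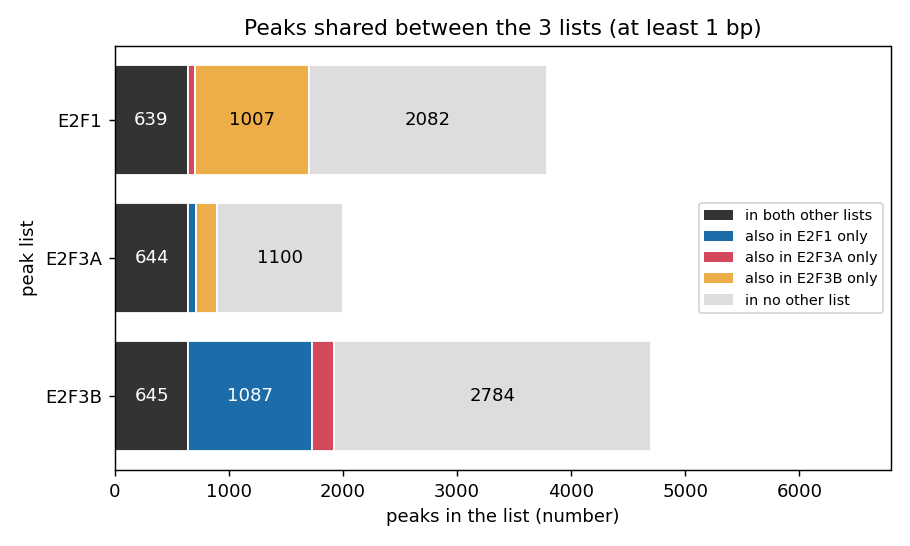
Number of peaks in each list (x axis) that overlapped a peak of both other lists, of 1 other list or of no other list by at least 1 bp, coloured by class. Between 639 and 645 peaks of each list lay in both others, and the unlabelled or narrow segments are the 59 E2F1 and 66 E2F3A peaks shared by these lists alone and the 188 peaks shared by E2F3A and E2F3B alone.

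All 3 pairs of lists shared more positions than shuffled peaks did. Of the E2F3A peaks, 710 (35.5%, interval 33.5 to 37.7) overlapped an E2F1 peak, against a mean of 0.149% when E2F3A peaks were shuffled within their chromosomes. A larger share of E2F3A peaks, 832 (41.6%, interval 39.5 to 43.8), overlapped an E2F3B peak, against 0.138% by shuffling. Of the E2F1 peaks, 1646 (43.5%, interval 41.9 to 45.0) overlapped an E2F3B peak, against 0.186%. In the opposite direction 18.4% of E2F1 peaks overlapped E2F3A, 36.8% of E2F3B peaks overlapped E2F1 and 17.7% of E2F3B peaks overlapped E2F3A. In these 6 counts none of the 1000 shuffles reached the observed share, with 0.551% as the highest shuffled share, so the one-sided permutation p was 0.0010 for each, the smallest that 1000 shuffles can give. Shuffled peaks could fall anywhere in the span of a chromosome, so the test cannot tell why the lists share positions. With peak centres within 100 bp, 20.4% of E2F3A peaks were in E2F1 and 31.4% in E2F3B, and 23.9% of E2F1 peaks were in E2F3B.

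The next comparison set the 2 E2F3 isoforms, precipitated with the same antibody, against E2F1. E2F1 was precipitated with another antibody, so an effect of the antibody cannot be told apart from one of the protein. E2F3 from the cells' own genes, or background of the shared antibody, could also add the same peaks to both E2F3 lists. Neither was separated here. E2F3A peaks lay in the E2F3B list more often than in the E2F1 list, with a difference of 6.11 percentage points (95% bootstrap interval over 5 Mb blocks 4.56 to 7.66). The difference was 11.01 points (9.03 to 12.97) with peak centres within 100 bp and 17.97 points (15.9 to 19.97) with 50% reciprocal overlap. E2F1 peaks were the widest, so both of these criteria are harder to meet for peaks that overlap an E2F1 peak. The larger differences therefore do not show a closer match of the isoforms. There were 188 E2F3A peaks shared with E2F3B and not E2F1, and 66 shared with E2F1 and not E2F3B. The E2F3B list was the longer one, and with the 1998 widest peaks of each list the difference was 2.90 points (1.14 to 4.69). At that equal length the pair with the most shared peaks was E2F1 and E2F3B, with 40.6% of E2F1 peaks in the E2F3B list (interval 38.5 to 42.8). E2F3A peaks reached 29.6% in E2F3B (27.6 to 31.6) and 26.7% in E2F1 (24.8 to 28.7) at the same length. This selection kept every E2F3A peak, narrow ones included, but only the widest E2F1 and E2F3B peaks, which were the most often shared, so it favoured the pair of E2F1 and E2F3B and does not rank the pairs.

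Sharing with one list went together with sharing with the other. Of the 710 E2F3A peaks that overlapped an E2F1 peak, 644 (90.7%, interval 88.3 to 92.6) also overlapped an E2F3B peak. Of the 1288 E2F3A peaks outside the E2F1 list, 188 (14.6%, interval 12.8 to 16.6) overlapped an E2F3B peak. E2F1 peaks gave the same picture, since 639 of the 698 shared with E2F3A (91.5%, interval 89.2 to 93.4) and 1007 of the 3089 outside E2F3A (32.6%, interval 31.0 to 34.3) were in the E2F3B list. Among the 1646 E2F1 peaks shared with E2F3B, 38.8% (36.5 to 41.2) were also called for E2F3A.

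Shared peaks were wider than unshared ones in every list. E2F1 peaks that overlapped an E2F3A peak had a median width of 741 bp, and the others 587 bp. E2F1 peaks shared with E2F3B had a median of 702 bp, against 568 bp, a difference of 134 bp that was 70.5 bp with peak centres within 100 bp. E2F3B peaks shared with E2F3A had a median of 455 bp, against 347 bp, and those shared with E2F1 424 bp, against 338 bp. The differences were smaller for E2F3A, at 368 against 333 bp for sharing with E2F1 and 364 against 333 bp for sharing with E2F3B. Each of these 6 differences had a two-sided permutation p of 1e-05 over the peaks of the list, also after Benjamini-Hochberg adjustment, which is the smallest that 100000 resamples can give. Peaks of a library are not replicates of the experiment, so these p-values describe the lists.

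When each list was divided into 10 width deciles, sharing was highest among the widest peaks. In the E2F3B list, sharing with another list lay between 25.9% and 29.8% in each of the 6 narrowest deciles and reached 79.8% (interval 75.9 to 83.2) in the widest. In the E2F1 list it was 34.3% (29.7 to 39.2) in the narrowest decile, lowest in the fifth at 24.0% (19.98 to 28.6), and 81.2% (76.97 to 84.8) in the widest. In the E2F3A list it was 43.5% (36.8 to 50.4) in the narrowest decile, lowest in the seventh at 30.5% (24.5 to 37.2), 73.5% (66.98 to 79.1) in the ninth and 92.0% (87.3 to 94.99) in the widest. Of the E2F3A peaks in that widest decile, 457 to 956 bp long, 81.4% lay in both other lists. The corresponding share was 42.6% for E2F1 and 44.3% for E2F3B.

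**Figure D2:**
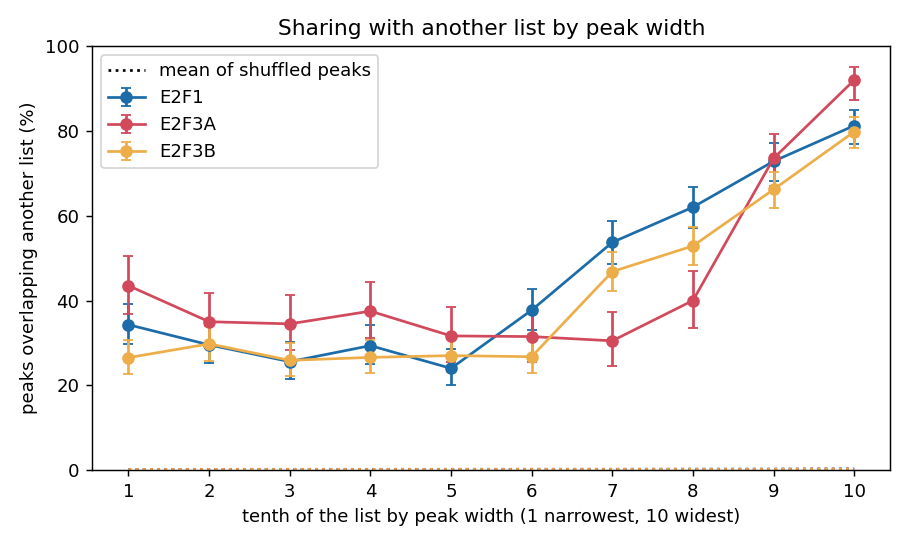
Share of peaks overlapping another list by at least 1 bp (y axis, %) in width deciles of each list, from the narrowest to the widest peaks (x axis). Points are observed shares with 95% Wilson intervals and dotted lines, close to 0, are means of 1000 shuffles, and each list reaches its highest share in the widest decile, at 81.2% for E2F1, 92.0% for E2F3A and 79.8% for E2F3B.

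The widest regions common to all 3 lists were the following, in mm9 coordinates. A region on chromosome 13 from 30076549 to 30078497 (1949 bp) held 1 E2F1 peak of 1676 bp, 1 E2F3A peak of 843 bp and 3 E2F3B peaks of 1344 bp in total. A region on chromosome 10 from 4540177 to 4542114 (1938 bp) held 1 E2F1 peak of 1722 bp, 2 E2F3A peaks of 1232 bp in total and 2 E2F3B peaks of 1561 bp in total. On chromosome 17, the region from 29231158 to 29233061 held peaks of 1904 bp for E2F1, 549 bp for E2F3A and 642 bp for E2F3B. Also on chromosome 17, the region from 48548199 to 48550096 held peaks of 1772 bp for E2F1, 319 bp for E2F3A and 1244 bp for E2F3B. On chromosome 1, the region from 88424133 to 88425990 held peaks of 1858 bp for E2F1, 557 bp for E2F3A and 906 bp for E2F3B. That these regions are common to all 3 lists depended on the criterion. With centres within 100 bp, at most 1 of the 3 pairs of lists matched in each, and 0 in the chromosome 17 region from 29231158. With 50% reciprocal overlap, all 3 pairs matched only in the chromosome 10 region. Genes and features at these positions were not analysed here, because no annotation of mm9 was used. As regions prone to artefact signal were not filtered out, a peak in all 3 lists does not by itself show binding of all 3 proteins.

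Among the 5 widest peaks of each list, most overlapped a peak of another protein by at least 1 bp. This count depended on the criterion, since 8 of the 15 peaks, among them all 5 of E2F1, had no match in another list with centres within 100 bp, and the 5 of E2F1 had none with 50% reciprocal overlap. The widest E2F1 peak, on chromosome 9 from 3021919 to 3023929 (2011 bp), was the only one of these 15 peaks that overlapped no peak of another list. Regions prone to artefact signal were not filtered out here, so this does not show a site bound by E2F1 alone. The E2F1 peaks on chromosome 17 from 35117584 to 35119537 (1954 bp) and on chromosome 14 from 19070109 to 19071982 (1874 bp) overlapped E2F3B and not E2F3A. The widest E2F3A peak, on chromosome 17 from 35978013 to 35978968 (956 bp), overlapped E2F3B and not E2F1. The other 4 of the widest E2F3A peaks were called for all 3 proteins and lay on chromosome 10 from 4540288 to 4541184, chromosome 8 from 36558000 to 36558884, chromosome 15 from 57966326 to 57967186 and chromosome 13 from 30077552 to 30078394. The widest E2F3B peak, on chromosome 1 from 74552043 to 74553594 (1552 bp), overlapped both other lists. So did the E2F3B peaks on chromosome 17 from 56442503 to 56443931 and from 48548853 to 48550096 and on chromosome 10 from 90643839 to 90645154. The E2F3B peak on chromosome 17 from 27692004 to 27693529 overlapped E2F1 and not E2F3A.

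Peak density differed between chromosomes in a like order in the 3 lists. Chromosome 15 held 3.23 E2F1 peaks, 1.59 E2F3A peaks and 2.80 E2F3B peaks per Mb, and chromosome 17 held 2.74, 1.48 and 3.02, in the same order of lists. The genome-wide densities were 1.49, 0.785 and 1.85 peaks per Mb. The X chromosome held the lowest densities, at 0.476 E2F1, 0.163 E2F3A and 0.495 E2F3B peaks per Mb, followed by chromosome 18 with 0.627, 0.251 and 0.790. Across the 20 chromosomes the density of E2F1 and E2F3B peaks had a Pearson r of 0.892 and a Spearman rho of 0.947. The values were 0.875 and 0.880 for E2F1 and E2F3A, and 0.897 and 0.904 for E2F3A and E2F3B. Every one of these 6 coefficients had a permutation p of 2e-05 or 1e-05 and, among the 10 relations computed across chromosomes, an adjusted p of 5e-05 or 3.3e-05. Without the 2 chromosomes farthest from the median density, r was 0.887, 0.770 and 0.877 in the same order of pairs. Chromosomes are not replicates, and the relation is across positions of these libraries. Shared peaks count in both lists of a pair, so the 2 densities are not independent and a positive relation is in part built in.

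**Figure D3:**
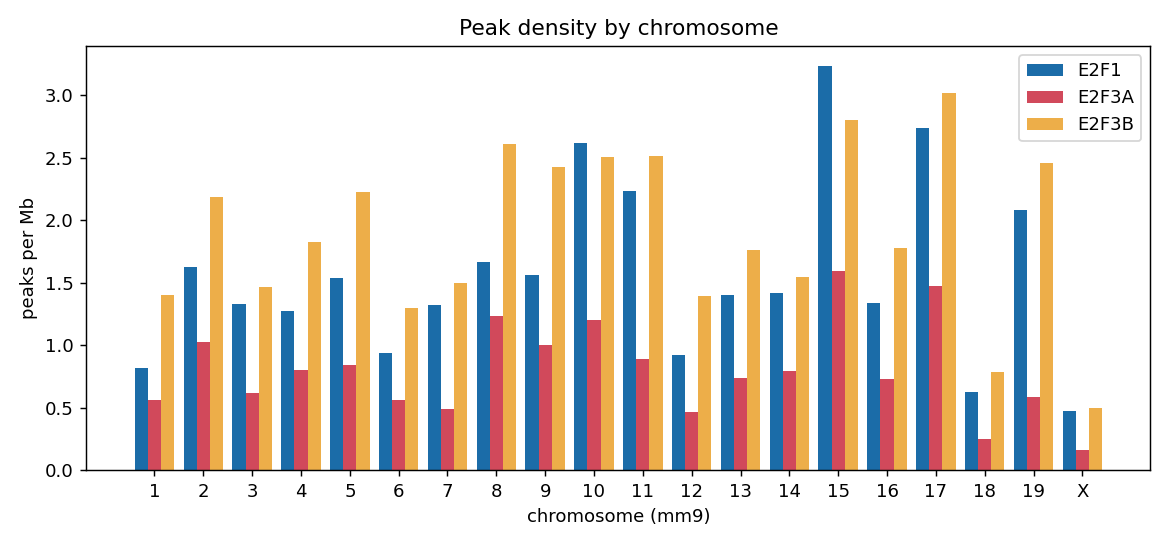
Peaks per Mb (y axis) on each mm9 chromosome (x axis) for the E2F1, E2F3A and E2F3B lists, 1 library each. Chromosome 15 stands highest for E2F1 (3.23) and E2F3A (1.59), chromosome 17 for E2F3B (3.02), and X lowest for each list.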

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

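The 6 shares of overlapping peaks stayed above chance with p = 0.0010 under each alternative run, and the 6 width differences kept their direction and an adjusted permutation p of 1e-05 with peak centres within 100 bp. That criterion took the difference for E2F1 peaks from 134 to 70.5 bp for sharing with E2F3B and from 154 to 105 bp for sharing with E2F3A. The size of the shares depended on the criterion. With centres within 100 bp, E2F3A peaks in E2F1 went from 35.5% to 20.4%, E2F1 peaks in E2F3B from 43.5% to 23.9%, and E2F3A peaks in E2F3B from 41.6% to 31.4%. With 50% reciprocal overlap they were 17.4%, 28.5% and 35.3%. E2F1 peaks were the widest, so criteria on the overlapped share of both peaks or on their centres are harder to meet for overlapping pairs with E2F1. The excess, added after the data were seen, of E2F3A peaks in E2F3B over E2F1, 6.11 points, became 11.01 points with centres within 100 bp, 18.0 points with reciprocal overlap and 2.90 points with the 1998 widest peaks of each list. It was 6.46 points within 500 bp and 6.11 points in the 50% widest peaks of each list. Restricting to autosomes and X removed 0 peaks and so tested nothing. Shifting peaks by 20 to 500 kb, an alternative chosen after seeing the data, raised the chance share of E2F1 peaks in E2F3B from 0.186% to 0.451%, and the highest share in any shifted set was 0.851%. Of the 20 named peaks and regions, 16 lost a match in at least 1 other list with centres within 100 bp and 10 with reciprocal overlap, and 0 within 500 bp. Each named common region holds a peak also named among the widest of a list, so these 20 are not separate positions. No paired analysis was possible because each group had 1 library. The missing depth and scores limit what an unshared peak shows, since a bound region below the caller's threshold in a list is counted as unshared.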

Other observations

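The tests on neighbouring peaks, on shared peaks alone, on counting error and on the overlap criterion for wide peaks were chosen after the result was seen, while those on copy number were written before it. A minority of the peaks that were not shared lay within 10 kb of a peak of another protein, more than among shuffled peaks. Of the 2972 E2F3B peaks that overlapped no E2F1 peak, 307 (10.3%) lay within 10 kb of one, against a mean of 2.94% in 200 shuffles. Of the 2141 E2F1 peaks outside the E2F3B list, 213 (9.95%) lay within 10 kb of an E2F3B peak, against 3.48%. Of the 1288 E2F3A peaks outside the E2F1 list, 86 (6.68%) lay within 10 kb of an E2F1 peak, against 2.92%. The one-sided permutation p was 0.0050 for each, the smallest that 200 shuffles can give. Within 100 kb the shares were 43.9%, 45.5% and 34.5%, against 21.7%, 24.2% and 21.5% by shuffling. Within 10 kb, 4.11% of E2F1 and 6.07% of E2F3B peaks outside the E2F3A list lay near an E2F3A peak, against 1.61% and 1.57%. For E2F3A peaks outside the E2F3B list the share was 8.32%, against 3.48%. Shuffled peaks could fall anywhere in the span of a chromosome, so the excess does not tell why these peaks lie near each other.

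The first pattern weighed is that wider peaks were shared more often. That wider peaks meet a 1 bp overlap more easily does not account for the whole of it, since with centres within 100 bp the widest decile was still shared more often than the 5 narrowest deciles together, at 47.6% against 20.5% for E2F1 (a difference of 27.1 points, the lowest of the lists), 75.9% against 29.7% for E2F3A and 53.4% against 17.1% for E2F3B. In each list the 95% Wilson intervals of these shares did not meet. That width stands for the strength of binding is a candidate explanation that could not be tested, because the files used hold no scores. Because regions prone to artefact signal were not filtered out, the wide shared peaks may include some of them. Sharing did not rise with width throughout: it was 34.3% in the narrowest E2F1 decile and 24.0% in the fifth, and 43.5% in the narrowest E2F3A decile and 30.5% in the seventh.

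The second pattern is the uneven density of peaks along chromosomes, high on 15 and 17 and low on X and 18. Calls found in 1 list alone do not account for the whole of it, since the peaks shared with another list were uneven too. Per Mb, shared peaks numbered 1.16 (E2F1), 0.631 (E2F3A) and 1.24 (E2F3B) on chromosome 15, and 0.219, 0.0815 and 0.238 on X. Their chi-square per degree of freedom against even spread was 10.3 or more in each list, and the largest of 10000 random draws was 3.15. These draws treated peaks as independent, so they do not cover clustering of peaks. More copies of some chromosomes in the cells may contribute, if more copies also widen peaks, which was not tested. Shared peaks were wider on dense chromosomes, with Spearman rho of 0.565 for E2F1, 0.813 for E2F3A and 0.624 for E2F3B (median 0.624). The adjusted permutation p was 0.018, 0.00012 and 0.0078 over 20 chromosomes. Pearson r was 0.640, 0.864 and 0.621, with permutation p of 0.0023, 1e-05 and 0.0035, and without the 2 chromosomes farthest from the median density r was 0.443, 0.834 and 0.662. For E2F1 the relation therefore rests in part on those 2 chromosomes. A chromosome richer in genes or in strong E2F sites would give the same relation and was not tested, and neither was a difference in the sequence to which reads can be aligned.

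The third pattern is that the ratio of E2F1 to E2F3B peaks, 0.805 genome-wide, ran from 0.584 on chromosome 1 (counting interval 0.480 to 0.712) to 1.15 on chromosome 15 (0.983 to 1.35). Counting error of independent peaks alone does not account for it. The chi-square over chromosomes was 72.8 and the largest of 100000 shuffles of the list names gave 54.5 (permutation p = 1e-05). These shuffles treated peaks as independent, although many were shared and others lay near each other, so the p-value does not cover clustering of peaks. A difference in chromosome copy number between these cells could produce it. If more copies also widen peaks, which was not tested and depends on the unknown control, shared peaks would be wider where the ratio is high. The ratio and the median log2 width ratio of shared peaks had a Spearman rho of -0.0541 (95% interval -0.485 to 0.398, permutation p = 0.82, adjusted p = 0.91) and a Pearson r of 0.128 (permutation p = 0.59). Without the 2 chromosomes farthest from the median ratio, rho was -0.344 and r was -0.0502. The interval over all 20 chromosomes is too wide to exclude it, and a difference in where E2F1 and E2F3B bind remains open and untested.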
